A study of Mus musculus with 36 samples.

How the data were processed

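Total RNA from 18 mouse cell lines was measured on 36 Affymetrix whole-genome mouse expression arrays, 2 arrays per line. Of these lines, 16 (E-1 to E-16) were grown from pancreatic tumors that had relapsed after doxycycline withdrawal, and they were cultured for 24 hours without doxycycline before RNA was prepared. The other 2 (iKras1 and iKras2) are parental control lines of the same genotype, cultured with doxycycline. In these mice doxycycline, through the rtTA activator placed at the ROSA locus, switches on a mutant Kras transgene.

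Per the submitters' processing notes, the authors made the deposited values with the affy package and RMA, which corrects the background, brings the arrays to a common distribution and summarizes the probes of each probe set. The versions are not given in the sources used here. The deposited values are on the log2 scale, from 2.01 to 14.4, with array medians between 5.32 and 5.43. An array has no read depth, and the number of arrays and lines and the signal over background limit the precision. Probe sets for the bacterial trp gene, whose RNA has no source in these cells, read between 2.63 and 3.89, which gives the level near which a value carries no information on a gene.

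Of the 45101 probe sets, the annotation gave 1 gene for 34958, several genes for 932 and none for 9211. Symbols were updated through the gene number for 34754 probe sets with the RefSeq gene table of assembly GRCm38.p6, which was used only for names and for the order of neighboring genes, and 204 kept the older symbol. No gene was named from a probe set with several genes. For each of the 18194 genes the probe set with the highest mean over all arrays was used, and 9012 of these genes had more than 1 probe set. Dim genes were not removed. Endogenous Kras has no named probe set here, and Kras was not analysed here, so the labels could not be checked on it and the 4 planned relations that need it were not computed.

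The arrays of a line correlated with r between 0.992 and 0.998 (median 0.997), and no 2 arrays held identical values. The labels do not say that the arrays of a line come from separate cultures, so p-values that rest on arrays measure only the spread between arrays, which may be technical. The series text names 8 tumors as the origin of the relapse lines and no label ties a line to a tumor, so p-values over lines are too small if lines share a tumor.

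The arrays fell into 2 technical batches, which no label gives. The batches were read from 6 probe sets for the 5′ ends of poly-A spike-in RNAs, bacterial transcripts added before labeling. Their mean was 7.15 ± 0.145 (SD, n = 20 arrays) in batch 1, which holds E-1 to E-4, E-9 to E-12 and both control lines, and 4.53 ± 0.207 (SD, n = 16 arrays) in batch 2, which holds E-5 to E-8 and E-13 to E-16, with a gap of 2.10 between the batches. A control probe set for 18S ribosomal RNA read 6.44 in batch 1 and 10.5 in batch 2, and the 3′ minus 5′ difference of Gapdh was −0.0632 and 0.261. Batch 2 holds 8 relapse lines and no control line, so for each of its lines batch and line cannot be told apart in a comparison with the controls. Values within batch 1, with 8 relapse and 2 control lines, are given beside the pooled ones for the genes named from the main comparison, for the fixed genes and for the lists that passed, but not for the members of lists. A fit with batch as a block gives the same differences as batch 1 alone by construction.

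The main comparison used the limma package on line means, 16 against 2, with lmFit and eBayes and Benjamini-Hochberg adjusted p under 0.05. A second limma fit, at the array level with a coefficient per line, gave the F test among the relapse lines, the difference of each relapse line from the mean of the control lines, and the difference between the control lines, the last 2 with an absolute log2 difference of at least 1. The comparisons of single lines share the control lines. The 33 gene lists were tested on line means with limma's camera at an inter-gene correlation of 0.01, with camera at an estimated correlation and limma's fry beside it. A list score is the mean over its members of the log2 value minus the gene's mean over the 18 lines. Relations used Pearson's r and Spearman's rho with 100000 permutations, or all permutations within a batch.

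The tests, the samples, the lists and the rule for named genes were fixed before the data were examined. The rule takes up to 12 genes with the largest positive and up to 12 with the largest negative log2 difference among those past the threshold whose 16 relapse line means lie on 1 side of both control lines, without predicted or clone-named genes. In each list it takes up to 4 members with the smallest adjusted p. It always takes Yap1, Birc2, Birc3 and Tead1 to Tead4. It adds the 12 genes with the largest SD among the relapse lines, and for each relapse line the gene farthest above and the gene farthest below the other 17 lines.

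The tests were run on simulated data with the arrays' own means and spread. For 16 against 2 line means over 18194 genes, 24 of 50 genes with a true log2 difference of 1 were recovered, 39 of 50 at 2, 50 of 50 at 4 and 47 of 50 at 6, with 6 false calls and no call of the wrong sign. The F test recovered 8047 of 9097 changed genes with 208 false calls. A shift of 2 put into the collagen and matrix list gave a camera adjusted p of 1.11e-12 and called 0 other lists. Genes and lines were drawn independently of each other in these data. In the real lists the estimated inter-gene correlation reached 0.661 (cholesterol genes). The simulation therefore does not show how often genes or lists that move together are called falsely. Alternatives covered the probe set per gene, a filter on dim genes, the unit of replication, the array used, the variance model, quantile and median scaling, thresholds, the list test and the lines included. The software was R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.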

Results

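Expression was measured in 16 pancreatic cancer cell lines that grew from tumors relapsing after doxycycline withdrawal. It was also measured in 2 parental lines cultured with doxycycline, which switches on the mutant Kras transgene. Each line had 2 arrays, so 32 arrays were from relapse lines without doxycycline and 4 from control lines with it. The series title places Yap1, a transcriptional coactivator of the Hippo pathway, at the center of the study. The comparisons below ask which genes differed between relapse and control lines, how Yap1 and its neighbors stood in each line, and how far the lines differed from each other.

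The largest differences among genes higher in relapse lines were those of Lhfp and Sparc. Sparc, which encodes a collagen-binding matrix glycoprotein, was 4.75 ± 0.89 log2 units higher (SE, 16 relapse and 2 control lines; 26.9-fold; limma adjusted p = 0.0433). Serpinh1, which encodes the collagen chaperone HSP47, was 2.16 ± 0.37 higher (SE; limma adjusted p = 0.0349). Lhfp, a tetraspan membrane protein gene, was 4.90 ± 0.91 higher (limma adjusted p = 0.0397). In all 3 genes every one of the 16 relapse lines lay above both control lines. Within batch 1 alone the differences were 4.56 for Sparc, 1.92 for Serpinh1 and 4.59 for Lhfp, with limma adjusted p = 0.156, 0.12 and 0.12. With batch as a block Serpinh1 passed (limma adjusted p = 0.0465), while Sparc and Lhfp did not (0.0877 and 0.0812). With the mean of all probe sets of a gene Sparc differed by 3.27 and did not pass (limma adjusted p = 0.0578).

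Of the genes higher in relapse lines, Atxn1 and Sox4 had the lowest p. Atxn1, which encodes the transcriptional repressor ataxin-1, was 2.67 ± 0.32 higher (SE; limma adjusted p = 0.00169), with 2.67 and an adjusted p of 0.00893 within batch 1. Sox4, an HMG-box transcription factor gene, was 1.41 ± 0.20 higher (SE; limma adjusted p = 0.00697), with 1.23 and an adjusted p of 0.031 within batch 1. These were the named genes that passed within batch 1. Zfp462, a zinc finger gene, was 3.16 higher, but its control values lay far apart, at 6.25 in iKras1 and 3.42 in iKras2, with an SD of 2.00 over the 2 lines. Its difference ran from 1.71 to 4.57 over the alternative settings. Arid4b and Kansl1l were 1.86 and 1.63 higher. The other higher genes were Hip1, an endocytic adaptor gene (3.18), Tut4, a terminal uridylyltransferase gene (2.52), Trim56, a ubiquitin ligase gene (1.32), and Fnbp1l, a membrane-bending adaptor gene (1.01). Within batch 1 the differences were 2.69 for Zfp462, 1.46 for Arid4b, 1.27 for Kansl1l, 2.94 for Hip1, 2.14 for Tut4, 1.13 for Trim56 and 0.97 for Fnbp1l, with limma adjusted p from 0.0517 (Trim56) to 0.162 (Zfp462). With batch as a block Hip1 and Fnbp1l did not pass (limma adjusted p = 0.0762 for both), nor did Epc2 (limma adjusted p = 0.0531). With the mean of all probe sets of a gene the differences were smaller, at 1.47 for Atxn1, 1.71 for Zfp462 and 1.02 for Arid4b, which still passed, and at 0.43 for Sox4, 1.15 for Hip1, 0.82 for Tut4 and 0.77 for Kansl1l, which did not (limma adjusted p = 0.48, 0.0837, 0.136 and 0.18).

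The genes that were lower in relapse lines were mostly of low level. Krt13, a keratin of stratified epithelia, differed by −2.77 ± 0.34 log2 units (SE; limma adjusted p = 0.00169), and its relapse mean of 3.87 lay at the level of the trp control probe sets. Hpcal4, a neuronal calcium sensor gene, differed by −1.77 and Mep1b, a metalloprotease gene, by −1.12, with relapse means of 3.50 and 3.26. Homer2, a scaffold protein gene, differed by −1.67, Ppp1r14d, a protein phosphatase inhibitor gene, by −1.46, Mnx1, a homeobox gene, by −1.08, and Otop2, a proton channel gene, by −0.90. Cysrt1 was the brightest of them, at 8.02 in relapse and 8.64 in control lines. Within batch 1 the differences were −2.59 for Krt13, −1.83 for Hpcal4, −1.57 for Homer2, −1.24 for Ppp1r14d, −0.99 for Mep1b, −1.04 for Mnx1, −0.73 for Otop2 and −0.63 for Cysrt1, with limma adjusted p from 0.0517 (Otop2) to 0.191 (Mnx1). With batch as a block Homer2 and Mnx1 did not pass (limma adjusted p = 0.0719 and 0.0784). Mnx1 was 3.52 in iKras1 and 4.91 in iKras2, so its difference was −0.38 without iKras2 and −1.77 without iKras1, and with the mean of all probe sets that of Krt13 was −1.25 and that of Cysrt1 −1.005. Homer2 differed by −2.24 there and did not pass (limma adjusted p = 0.0506).

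**Figure D1:**
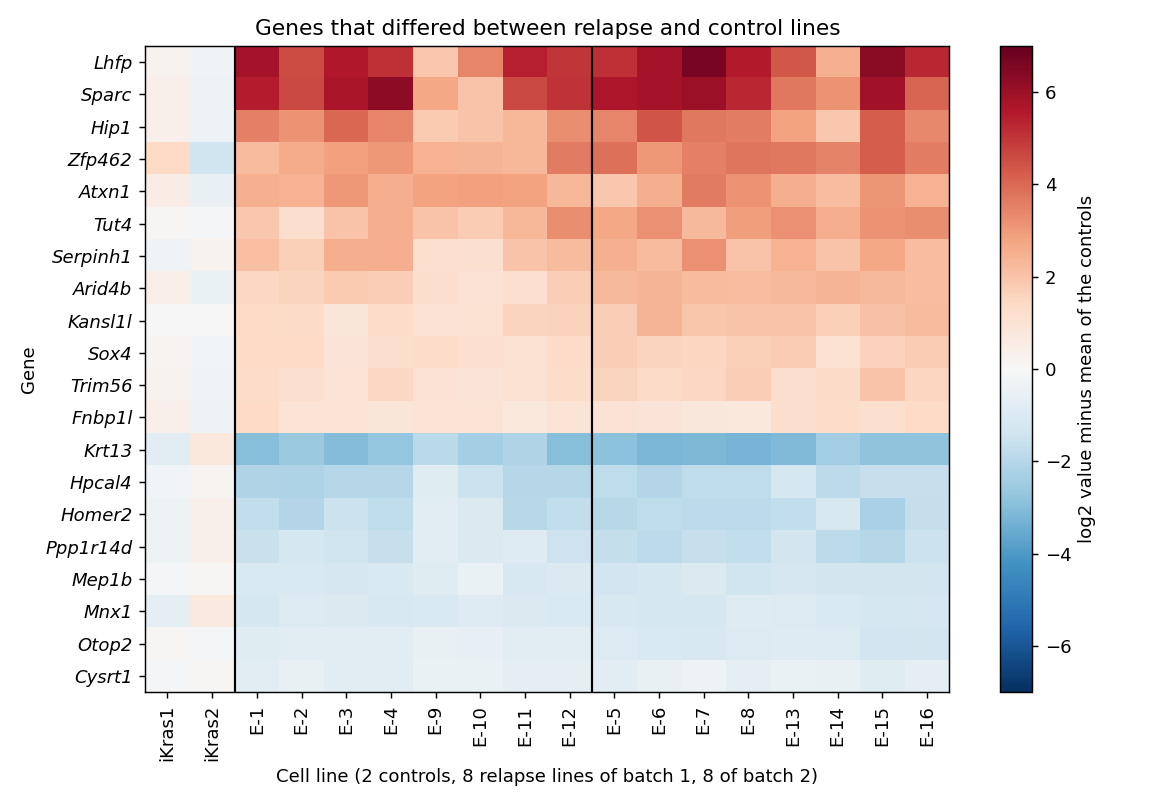
Color gives the log2 value of each line (mean of 2 arrays) minus the mean of the 2 control lines, for the 20 named genes in rows and the 18 lines in columns, with controls first, then the relapse lines of batch 1 and batch 2. Every relapse line lay on 1 side of both controls for each gene, from 6.65 above the control mean (Lhfp in E-7) to 3.23 below it (Krt13 in E-8).

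In all, 22 of 18194 genes passed, 14 higher and 8 lower, and 18 of them differed by at least 1 log2 unit. All 22 had every relapse line on 1 side of both control lines and the same direction within batch 1. Over all genes, 1188 (6.53%) had that separation. If every pair of the 18 lines were equally likely to stand apart, 1.31% of genes would have it. The control lines were the most alike of all pairs of lines (r = 0.992 across genes) and share batch 1, so that figure does not measure chance here. With batch as a block 21 genes passed, 15 of them shared with the pooled fit, and within batch 1 alone 6 passed, 2 of them shared. The count rests on the control lines: without iKras1 it was 5 genes and without iKras2 it was 0, although 2425 genes had an unadjusted p under 0.05 in the limma fit of all lines. Without E-8, E-12 or E-16 it was 7, 9 and 6, and without E-9 or E-10 it was 69 and 57.

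Of the 33 gene lists, 14 moved by camera, 9 up and 5 down. Within batch 1 alone 10 lists passed by camera, but 0 passed there with an estimated correlation. The camera adjusted p there was then 0.277 for TGF-beta response and YAP/TEAD target genes and 0.311 for collagen and matrix genes. Mesenchymal transition genes rose as a list, with a median difference of 1.44 over 18 measured members and 18 members positive (camera adjusted p = 5.61e-09; adjusted p = 0.149 with an estimated correlation). Of its members 1, Sparc, passed over all genes, and 7 rose when adjusted over the list alone, among them Fn1, the fibronectin gene (2.48), Mmp14, a membrane collagenase gene (1.23), and Twist1, a mesenchymal transcription factor gene (2.80). The list's score lay above both controls in all 16 lines. The median of the list within batch 1 was 1.30 (camera adjusted p = 2.86e-08, and 0.31 with an estimated correlation). Collagen and matrix genes had a median of 1.68 over 19 members (camera adjusted p = 0.000198; adjusted p = 0.21 with an estimated correlation), with 14 lines above both controls and 1 line, E-14, below, and a median of 1.36 within batch 1 (camera adjusted p = 0.000385). None of them passed over all genes and 1, Col6a1 (3.24), passed adjusted over the list alone, while Thbs1 differed by 3.37 and Fbln2 by 1.68. TGF-beta response genes rose as a list by a median of 0.73 (16 members; camera adjusted p = 1.13e-05; adjusted p = 0.135 with an estimated correlation), and 4 passed adjusted over the list alone: Skil, a feedback inhibitor of SMAD signaling (1.18), the receptor gene Tgfbr1 (1.39), the activin subunit gene Inhba (2.80) and Id3 (1.78). Within batch 1 its median was 0.44 (camera adjusted p = 0.000385).

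Fibroblast and stellate cell markers rose as a list by a median of 0.71 over 15 members (camera adjusted p = 0.01; adjusted p = 0.343 with an estimated correlation), and their score was above both controls in 16 lines. The markers include Dcn, Lum, Col1a1, Col3a1 and Postn, which are also in the collagen and matrix list, so the results of these lists are not independent. Within batch 1 their adjusted p was 0.0661. None of the 15 passed singly. Acta2, smooth muscle actin, differed by 3.50 ± 1.41 (SE), Col1a1 by 2.67 ± 1.40, Col3a1 by 4.03 ± 2.15 and Pdgfra by 2.42 ± 1.43.

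Epithelial genes fell as a list, with a median of −1.21 over 25 members (camera adjusted p = 0.0382; adjusted p = 0.578 with an estimated correlation), and no member passed. The epithelial transcription factor gene Elf3 differed by −1.88 and lay below both controls in 16 lines. Tjp3, a tight junction gene, differed by −1.49 and Pkp3, a desmosome gene, by −0.89. The list score lay below both controls in 14 lines and above them in E-13 and E-16, both of batch 2. The median within batch 1 was −1.21 (camera adjusted p = 0.00139). Genes of pancreatic intraepithelial neoplasia and gastrointestinal identity also fell as a list, by a median of −1.07 over 18 members (camera adjusted p = 0.0124; adjusted p = 0.537 with an estimated correlation). Onecut3 (−0.70) passed adjusted over the list alone, while the mucin gene Muc5ac differed by −2.06 and the trefoil factor gene Tff1 by −2.77. The median of this list within batch 1 was −1.05 (camera adjusted p = 0.0153).

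Hippo pathway and TEAD components rose as a list by a median of 0.44 over 19 members (camera adjusted p = 0.000278), and this was the 1 list that also passed with an estimated correlation (adjusted p = 0.0344). Within batch 1 the median was 0.41 (camera adjusted p = 0.000385), but with an estimated correlation there the list did not pass (adjusted p = 0.084). Its score lay above both controls in 16 lines. Its member Vgll4 followed the batches, from 6.55 to 6.99 in batch 1, controls included, and from 8.44 to 9.42 in batch 2. Amotl1, an angiomotin family gene, differed by 1.90 ± 0.50 (SE) and Mob1b, a LATS kinase coactivator gene, by 0.87 ± 0.26, and both passed adjusted over the list alone. Among the TEAD factors that carry YAP1 to DNA, Tead1 differed by 0.66 ± 0.22 (SE; limma adjusted p = 0.227), Tead2 by 1.25 ± 0.72, Tead3 by −0.07 ± 0.11 and Tead4 by −0.53 ± 0.23, none past the threshold. Within batch 1 they differed by 0.55, 0.70, 0.01 and −0.31. With the mean of all probe sets Tead1 differed by 0.27 (limma adjusted p = 0.518) and Tead4 by −0.70 (limma adjusted p = 0.34). YAP/TEAD target genes rose as a list by a median of 0.39 over 25 members (camera adjusted p = 0.00144; adjusted p = 0.149 with an estimated correlation), with 15 lines above both controls and E-4 below, and a median of 0.46 within batch 1 (camera adjusted p = 1.86e-05). No target passed singly, over all genes or over the list alone. The largest evidence among them was for Ccn1 (1.64 ± 0.51, SE), Tgfb2 (2.62 ± 0.85) and Crim1 (1.28 ± 0.48), whose limma adjusted p values were 0.198, 0.218 and 0.276.

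Ras isoforms, regulators and effectors rose as a list by a median of 0.23 over 16 members (camera adjusted p = 0.01; adjusted p = 0.149 with an estimated correlation; adjusted p = 0.0661 within batch 1). Its measured members did not include Kras, Hras, Raf1, Mapk1 or Mapk3. The 2 members that passed over the list alone were Rasa1, which encodes a GTPase-activating protein that turns Ras off (1.37), and Rras (0.59). Lysosome and autophagy genes rose as a list by a median of 0.33 over 19 members (camera adjusted p = 0.00699; adjusted p = 0.149 with an estimated correlation), led by Hexa (2.02) and Lamp2 (1.58), with a median of 0.25 within batch 1 (camera adjusted p = 0.00132). Interferon response genes rose as a list by a median of 0.29 over 18 members (camera adjusted p = 0.0159; adjusted p = 0.511 with an estimated correlation; adjusted p = 0.09 within batch 1), and Ifit2 differed by 2.51. ERK pathway output genes did not pass, with a median of −0.19 over 22 members (camera adjusted p = 0.716). Spry4 differed by −0.95 and Egr1 by 1.46.

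The list of cholesterol synthesis and uptake genes fell by a median of −0.72 over 19 measured members (camera adjusted p = 0.0323, and 0.578 with an estimated correlation). Hmgcr, Dhcr24 and the uptake genes Ldlr and Pcsk9 were not among those measured, so uptake through them was not covered. The batches differed for this list. Within batch 1 the median was −1.22 (camera adjusted p = 3.46e-12, and 0.277 with an estimated correlation). All 8 relapse lines of batch 1 lay below both controls. In batch 2, where no control was hybridized, 4 lines lay above and 3 below. The kinase gene Mvk (−0.84) passed adjusted over the list alone and Fdps differed by −1.14. Proliferation genes fell as a list by a median of −0.47 over 24 members (camera adjusted p = 0.01; adjusted p = 0.537 with an estimated correlation). Within batch 1 their median was −0.13 with an adjusted p of 0.09. Leukocyte markers fell as a list by a median of −0.20 over 14 members (camera adjusted p = 0.0181; adjusted p = 0.343 with an estimated correlation). Cd79b (−0.30) and Lyz2 (−0.21) were among them, at levels of 3.85 and 5.29 in relapse lines, and the list's median within batch 1 was −0.12 (camera adjusted p = 0.0346). The median of all genes was −0.07.

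The other 19 lists did not pass. Receptor tyrosine kinases came nearest, with a median of 0.39 (camera adjusted p = 0.0543), and Igf1r (1.03), Egfr (1.49) and Ntrk2 (−0.26) passed adjusted over the list alone. The medians and camera adjusted p were −0.23 and 0.43 for glycolysis, −0.32 and 0.602 for the hexosamine and pentose phosphate pathways, −0.20 and 0.368 for oxidative phosphorylation, in which Uqcrc1 (−0.47) passed over the list alone, −0.18 and 0.888 for the mitochondrial stress response, whose mean of 0.02 had the other sign, and −0.22 and 0.093 for MYC and ribosome biogenesis. They were −0.12 and 0.466 for p53 targets, whose mean was 0.09, 0.14 and 0.0935 for cell cycle inhibitors, 0.23 and 0.232 for inflammatory cytokines, in which Csf3 (−1.02) did, and 0.07 and 0.109 for hypoxia, in which Bnip3 (1.59) passed over the list alone. They were −0.16 and 0.093 for acinar genes, in which Cela3b (−0.33) did, −2.31 and 0.466 for duct, −0.10 and 0.602 for endothelial and −0.05 and 0.357 for endocrine and neural genes. They were 0.04 and 0.548 for stem-like genes, −0.17 and 0.368 for sex-linked genes, 0.08 and 0.093 for the genes near Yap1, and 0.47 and 0.084 for the genes near Kras.

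**Figure D2:**
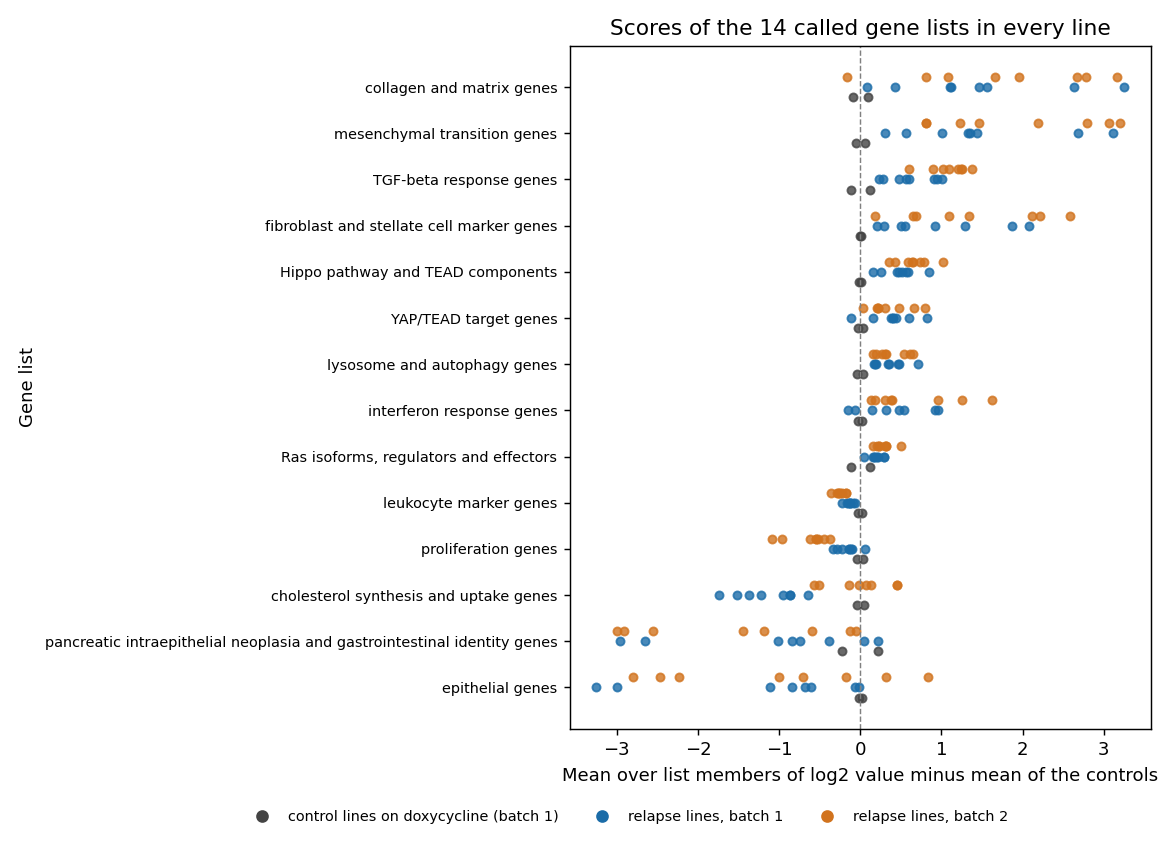
Each point is 1 cell line. The horizontal axis gives the mean over the members of a list of the log2 value minus the mean of the 2 control lines, and the rows are the 14 lists that passed, ordered by their median difference, with control lines, batch 1 and batch 2 set at 3 heights. All 16 relapse lines lay above both controls for the mesenchymal list, and for cholesterol genes the 8 lines of batch 1 lay below both.

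Yap1 stood apart in 3 relapse lines and did not pass between the groups of lines as a whole. Yap1 was 12.75 in E-1, 12.85 in E-2 and 12.99 in E-5, against 9.86 in iKras1 and 9.97 in iKras2, which is 7.14, 7.65 and 8.45 times the control mean. E-12 followed at 11.38, and the remaining 12 relapse lines lay between 9.79 and 10.84. Of the 16 relapse lines 13 lay above both controls and 1 below. Over all lines the difference was 0.91 ± 0.75 (SE; limma adjusted p = 0.594), and within batch 1 it was 1.01 (limma adjusted p = 0.687). The other Yap1 probe set also had E-1, E-2 and E-5 on top, at 11.07, 11.28 and 11.10, which is 6.92, 8.02 and 7.08 times the control mean. The probe sets differed in the other lines: on the other one 10 relapse lines lay below the control mean, down to 0.32 times it in E-14, against 1 line on the probe set used here, and its difference over all lines was 0.21 (limma adjusted p = 0.934).

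The genes beside Yap1 were high in the same 3 lines. Birc2, which encodes the apoptosis inhibitor cIAP1 and lies beside Birc3, the gene next to Yap1, exceeded the control mean by 3.21 in E-1, 4.05 in E-2 and 4.13 in E-5. Birc3, which encodes cIAP2, exceeded it by 3.05, 3.34 and 4.04, and Tmem123 by 3.19, 3.55 and 3.86. Dcun1d5, Dync2h1 and Mmp10 exceeded it in E-5 by 2.63, 2.14 and 3.38, and Mmp10 exceeded it by 2.08 in E-2 and 1.04 in E-1. The matrix metalloproteinase gene Mmp13 exceeded it by 5.25 in E-5 and 4.19 in E-2, but also by 4.74 in E-8, where Yap1 was 10.76, and by 0.98 in E-1. Over all lines Birc2 had a mean of 8.67 in relapse and 7.47 in control lines (SE of the difference 0.95; limma adjusted p = 0.578). Birc3 differed by 1.59 ± 0.74 (SE; limma adjusted p = 0.368), and on the probe set used here it lay above both controls in 16 of 16 relapse lines. On the other Birc3 probe set E-5 was highest (6.51), while E-13 (4.82) and E-14 (4.76) lay below both controls. With the mean of all probe sets Birc3 differed by 0.96 (limma adjusted p = 0.432). Within batch 1, on the probe sets used here, Birc2 and Birc3 differed by 1.33 and 1.5 (limma adjusted p = 0.653 and 0.485).

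**Figure D3:**
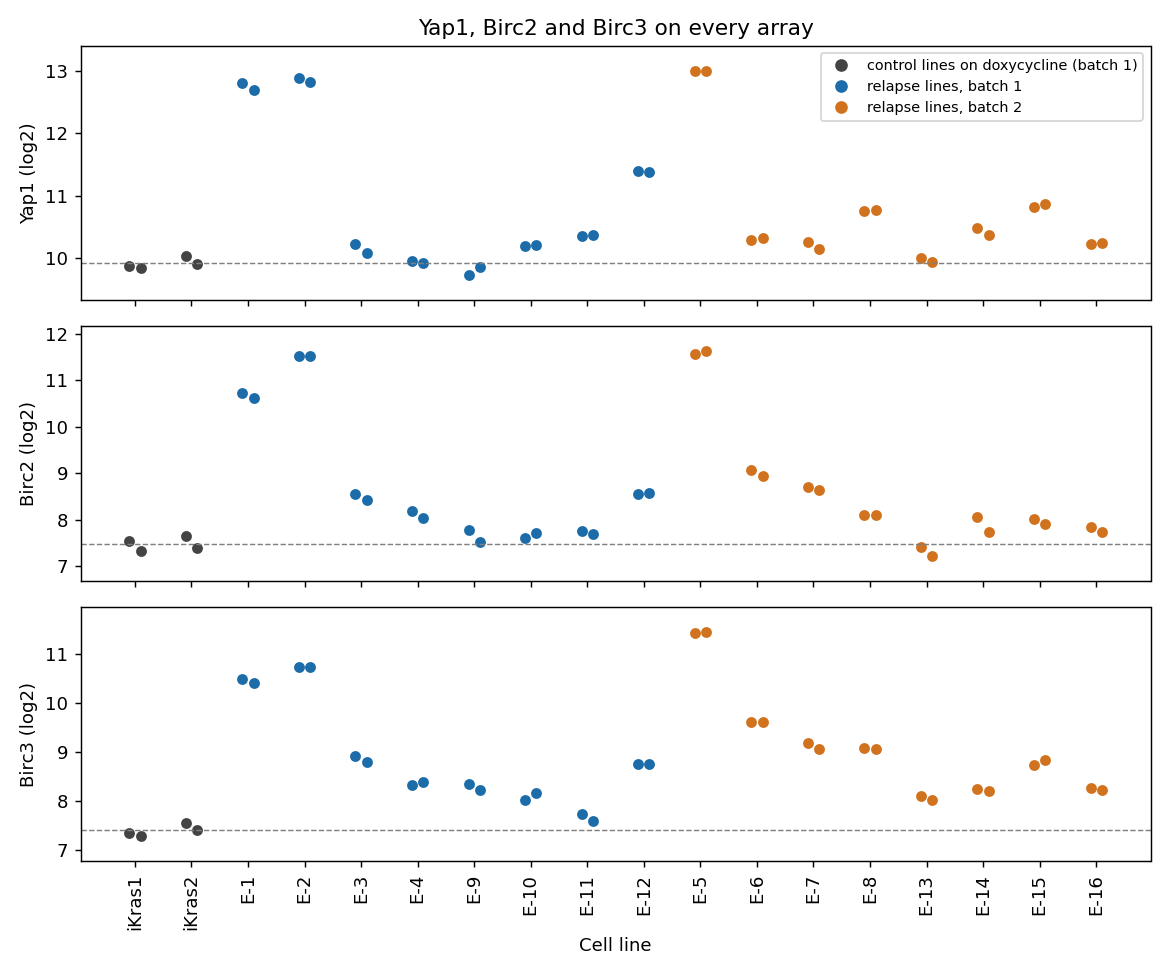
Log2 value of Yap1, Birc2 and Birc3 on every array, with 2 points per line and the dashed line at the mean of the 2 control lines. E-1, E-2 and E-5 lay highest for all 3 genes, with line means from 12.75 to 12.99 for Yap1.

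Since the Yap1 values split into 3 and 13 lines, with a gap of 1.37 that is 42.7% of their range, no correlation was computed over all 16. Over the other 13 lines Yap1, from the probe set used here, had r = 0.34 with Birc2 (permutation p = 0.254), 0.30 with Birc3 (p = 0.316), 0.29 with the YAP/TEAD target score (p = 0.334) and 0.08 with the proliferation score (p = 0.807). Spearman's rho was 0.35, 0.20, 0.17 and −0.16, with permutation p = 0.246, 0.503, 0.579 and 0.592. After adjustment over these 4 relations the lowest p was 0.446 for r and 0.592 for rho. Without E-12 and E-15, the lines farthest from the median, r was 0.25, 0.29, 0.39 and −0.33. Within batch 1 (6 lines) r was 0.59, 0.30, 0.35 and 0.21, with exact p = 0.201, 0.556, 0.449 and 0.785, and within batch 2 (7 lines) it was 0.12, 0.32, 0.21 and 0.37, with exact p = 0.795, 0.477, 0.665 and 0.41.

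The relapse lines differed widely from each other. Among the 12 genes with the largest spread, epithelial and gastrointestinal genes were near the array floor in some lines and among the brightest genes in others. Cdh1, which encodes E-cadherin, was 3.37 in E-3, 3.59 in E-4, 3.92 in E-7, 5.65 in E-15 and 5.88 in E-6, and between 9.49 and 11.49 in the other 11 lines, against a control mean of 11.06. The duct keratin gene Krt7 was under 6 in the same 5 lines and Krt19 was 4.88, 4.87, 4.99, 6.57 and 4.58 in them. Lgals2, Lgals4, Tspan8, Anxa13, Anxa10 and Apob ranged over 8.34 to 9.87 log2 units. The fibrillar collagen gene Col1a2 reached 14.05 in E-3, 14.06 in E-4 and 13.92 in E-7, against a control mean of 5.49, and Col3a1 reached 13.31 in E-7, 13.14 in E-6 and 12.70 in E-15. Bgn, the biglycan gene, ranged from 5.37 in E-14 to 13.27 in E-3. By the limma F test 15082 of 18194 genes (82.9%) differed among the 16 lines, 11674 among the 8 lines of batch 1 and 13152 among the 8 of batch 2, with 11062 shared. The median share of a gene's variance that lay between lines was 0.901, and this test sets lines against the spread between 2 arrays of a line. That share includes the difference between the batches, which held a median of 0.164 of the variance of the line means.

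**Figure D4:**
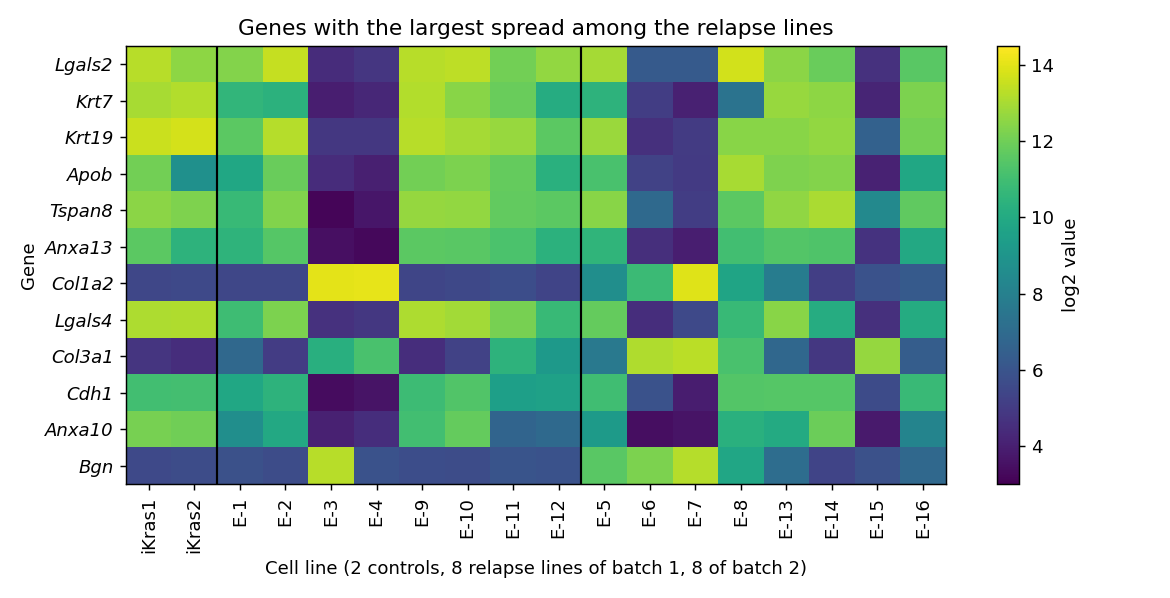
Color gives the log2 value of each line (mean of 2 arrays) for the 12 genes with the largest spread among relapse lines, in rows, and the 18 lines in columns, with controls first, then batch 1 and batch 2. Cdh1 was under 6 in E-3, E-4, E-6, E-7 and E-15, and Col1a2 was highest in E-3, E-4 and E-7.

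For each relapse line the gene farthest above and the gene farthest below the other 17 lines were taken, so every line has them by construction. Values were compared across both batches without adjustment. Some of these genes were also bright elsewhere, as the next highest line was at 9.75 for Lpl and 9.25 for Rhox5. In E-2 the gene Bex1 was 11.27, which is 5.69 above the next highest of the 18 lines. Stmn2, a neuronal microtubule regulator gene, was 12.51 in E-4, a gap of 4.74. Cyp7b1, an oxysterol hydroxylase gene, was 9.31 in E-3 (gap 4.38), and Tcfl5 was 7.42 in E-15 (gap 4.13). The gap was 3.70 for Atp2b2 in E-9, 3.47 for the lubricin gene Prg4 in E-8, 3.10 for the enkephalin precursor gene Penk in E-6, 3.04 for the ligand gene Gas6 in E-11, 2.99 for Enpep in E-14, 2.94 for B4galnt2 in E-13, 2.89 for Col6a3 in E-7, 2.57 for the lipase gene Lpl in E-5, 2.30 for Dlk1 in E-1, 1.97 for Ces2b in E-16, 1.94 for the X-linked homeobox gene Rhox5 in E-10 and 1.39 for Clca3b in E-12. On the low side, the keratin gene Krt8 was 5.66 in E-3 and 11.42 or more in the other 17 lines, and the p53 target Rps27l was 6.56 in E-12 and 11.51 or more elsewhere. The gap below was 3.64 for Maoa in E-16, 3.44 for Perp in E-15, 3.41 for Socs2 in E-4, 3.24 for Scd1 in E-1 and 2.99 for Hs6st2 in E-13. In the other 9 lines it was between 1.10 (Dnajc12 in E-8) and 2.56 (Tnfrsf21 in E-7), with Epb41l4a in E-14 (2.56), Fkbp11 in E-6 (2.16), Wtip in E-9 (1.85), Rnf130 in E-11 (1.66), Lamb1 in E-2 (1.63), Mecom in E-5 (1.55) and Golm2 in E-10 (1.37) between them.

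Each relapse line was then set against the mean of both controls. E-9 and E-10 were nearest to the controls, with 572 genes past the threshold in each, and they correlated with iKras1 at r = 0.987 and 0.986 across genes, which are not independent replicates. In batch 1 the counts ran from these to 2426 in E-4, with a median of 1333. In batch 2 they ran from 1795 in E-14 to 3592 in E-7, with a median of 2216.5, and there the batch and the line cannot be told apart. Between the control lines 251 genes differed, 143 higher in iKras1. The claudin gene Cldn18 was 11.05 in iKras1 and 5.18 in iKras2, and the aquaporin gene Aqp5 was 6.48 and 9.98. The errors of these comparisons cover only the spread between arrays of a line.

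**Figure D5:**
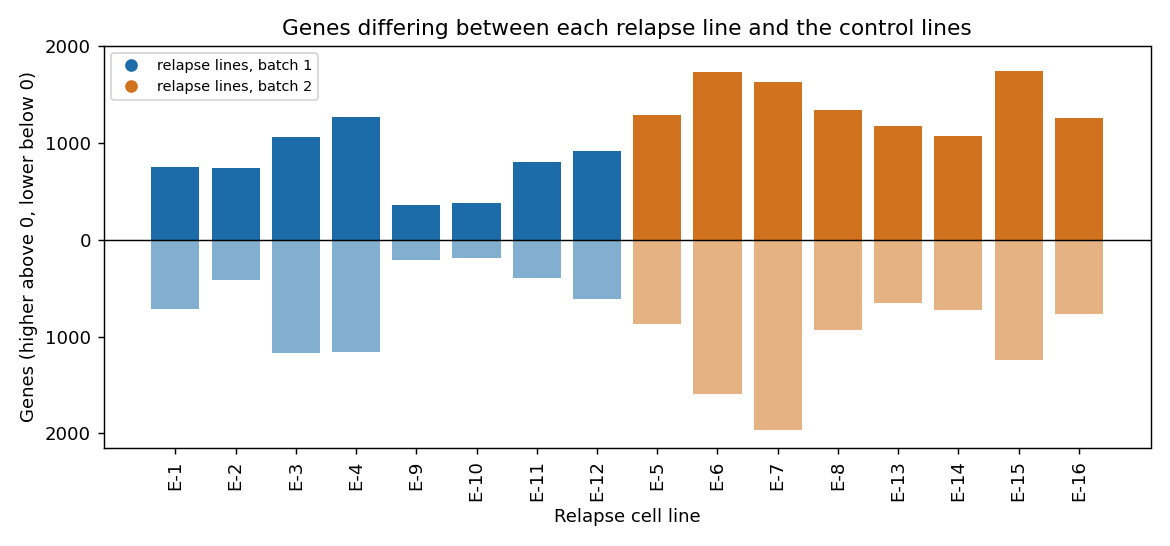
Bars give the number of genes per relapse line with adjusted p under 0.05 and a log2 difference of at least 1 from the mean of the controls, higher genes above 0 and lower genes below 0, with the lines of batch 1 at the left and of batch 2 at the right. E-9 and E-10 had 572 each and E-7 had 3592.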

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

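The tests of batch, fibroblasts, relapse origin, the single Yap1 probe set, the rise of the region around Yap1 and the chance run of neighboring genes below were chosen only after the result was seen, while the splits of the lines and the test of the second probe sets around Gt(ROSA)26Sor were written before.

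The 22 genes that differed between relapse and control lines were set against other splits of the 18 lines into 16 and 2, and 9 of 100 splits, the real one among them, gave as many genes, with 538 for the highest of the others (E-6 and E-7 against the rest), so chance cannot be excluded. Within batch 1, where the real count was 6, 6 of 45 splits, again with the real one among them, gave as many, with 1251 for the highest (E-3 and E-4 against the rest), so chance cannot be excluded there either. Splits that call many times the real count point to a structure among the relapse lines.

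Mesenchymal and matrix genes were higher as lists in relapse lines. Within batch 1, which holds the controls, the mesenchymal median was 1.30, which argues against the batch difference as the whole cause. With an estimated correlation the mesenchymal list did not pass within batch 1 (camera adjusted p = 0.31). Fibroblasts in the cultures would bring Col1a2 together with Sparc, but 9 relapse lines had Sparc at least 1 log2 unit above the control mean and Col1a2 less than 1 above it, which argues against fibroblasts as the source in those lines. Other collagens were high in some of the 9 without Col1a2, with Col3a1 8.05 and Col1a1 5.31 above the control mean in E-15, Col3a1 5.80 in E-11 and 4.51 in E-12, and Col1a1 3.75 in E-1. In the lines with Col1a2 above the control level fibroblasts stay open, since Krt8 there ranged from −7.94 in E-3 to 0.15 in E-5, with 0.08 in E-8 and E-13, and a high baseline of Krt8 would hide a small share of other cells. Relapse origin, doxycycline itself and the choice of control lines cannot be told apart, because 0 relapse lines had arrays on doxycycline and only 2 control lines were measured.

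Yap1 and its neighbors were high in E-1, E-2 and E-5, which lie in both batches, and Yap1 in each exceeded the highest other line of its batch by at least 1.37. These lines were picked by that gap in Yap1, so the result could not come out otherwise and is no test of the batch difference. The other Yap1 probe set, which was not used to pick them, exceeded the highest other line of the batch by at least 1.36. This argues against a single aberrant probe set. A rise of the whole region stays open: second probe sets of Yap1, Tmem123 and Birc3 had a median of at least 2.13 above the batch median, but these genes were already seen to be high, so this is no separate test. The median over the 11 genes centered on Yap1 was 2.51 in E-5, beyond all shuffles of the gene order, but 0.29 in E-1 and 0.81 in E-2, and Cep126, 2 genes from Yap1, lay at 0.21, −0.12 and 0.14 in E-1, E-2 and E-5. Among the genes scanned, those raised together ran from Tmem123 to Cfap300 in E-1 and E-2. In E-5 they also held Dcun1d5, at 2.74 above the batch median, so the stretch was not the same in these lines. A gain of a short stretch around Yap1 is a hypothesis that was not tested, and no DNA measurement was analysed here.

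Genes around Gt(ROSA)26Sor, the locus that holds the rtTA activator by the genotype label, were high together in E-10, E-11, E-12, E-15 and E-16, and less so in E-9, while E-13 had Setd5 at 2.72 above the batch median with Mtmr14 at −0.29, and Gt(ROSA)26Sor itself lay at −5.23 in E-5, −2.64 in E-4 and −2.41 in E-7. Among windows of 11 neighboring genes that hold Gt(ROSA)26Sor the highest median was 3.46 in E-12, 2.60 in E-15, 2.27 in E-10, 1.68 in E-11 and 1.36 in E-16, and the highest in 100 shuffles of the gene order was 1.30, which argues against a chance run in these 5 lines, while the window of E-9 centered there had 1.19, and adjacent ones without the locus had 1.31 in E-9 and 1.44 in E-16. Of these lines 2 lie in batch 2 and 3 in batch 1. The batch median of each gene was subtracted before the scan, so this is no test of the batch difference. A rise of the whole region stays open: the lower of the medians over 7 second probe sets in E-12 and E-15 was 2.70, but they belong to genes picked because they were high there, so this is no separate test. A gain of DNA at this locus is a hypothesis that was not tested, and no biological explanation was tested.

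Some control arrays lay far from the other 3. The gap to the nearest array as a share of the range of the 4 arrays was 0.919 for the oxidative phosphorylation score, 0.865 for the acinar score, 0.915 for Arid4b and 0.858 for Fnbp1l, each with array 2 of iKras2 farthest, 0.861 for the proliferation score with array 1 of iKras2, and 0.835 for Otop2 with array 1 of iKras1. Of 60 measures tested, 6 passed Dixon's 95% critical value, where independent arrays and measures would give about 3 by chance. The 4 arrays are pairs from 2 lines and the measures overlap, so that figure does not measure chance here. The arrays of iKras2 were the least alike of any line (r = 0.992).

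The F test called 15082 genes as different among the relapse lines, which marks a difference between groups. For 5 lists some lines lay above all 4 control arrays and others below all 4, a difference that was not tested. Cholesterol genes had 4 lines above (E-5, E-7, E-8 and E-14) and 11 below, and epithelial genes 2 above (E-13 and E-16) and 13 below. For YAP/TEAD targets 14 lay above and 1 below (E-4), for collagen and matrix genes 14 and 1 (E-14), and for interferon response genes 14 and 1 (E-1). All lines above for cholesterol and epithelial genes, and E-14, lie in batch 2, which holds no control line. For these lines batch and line cannot be told apart, while E-4 and E-1 lie in batch 1.

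Among 10092 probe sets without a single gene, which no comparison used, 11 differed between relapse and control lines by limma, 2 higher and 9 lower, 3 of them also called within batch 1, where 7 were called in all. The largest differences were −5.28 for 1422071_at (adjusted p = 0.00435) and −4.15 for 1452426_x_at (adjusted p = 0.00198).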

How the results depend on the processing

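The batch alternatives, the relations within a batch and iKras2 from its array 1 alone were tests chosen after seeing the data, and the others were fixed before. No called result reversed, and the cause of the changes below was not tested unless named. The 22 genes between relapse and control lines (14 higher, 8 lower) became 12 with genes above the median mean alone (12 higher, 0 lower), 5 at an adjusted p of 0.01, 6 with batch 1 alone, which has fewer lines, 123 with array 2 of each line alone (17 with array 1), and 417 with arrays in place of line means and the line as a random block. With a replicate block added to that fit 369 genes passed. The array numbers only share a number, with a median correlation of −0.0017 over 153 pairs of lines, 12 of them over 0.1. Leaving out 1 line gave 0 (without iKras2) to 69 (without E-9), with the lone control line then taken to vary like the others. The count was 28 (14 higher, 14 lower) with median centering, 24 with quantile scaling, 20 with mean probe sets, 31 with trended and robust variance, 21 with batch as a block and 18 with iKras2 from its array 1 alone. Atxn1 passed in 29 of 30 settings and Krt13 in 27 of 29, but Lhfp in 16, Fnbp1l in 15, Sparc in 14 and Kansl1l in 11 of 30, and Mnx1 in 14 of 29, with adjusted p up to 0.987.

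The count among relapse lines was 9035 with genes above the median mean, of fewer genes tested, 15032 with the replicate block, and 14823 to 15120 leaving out 1 line. The control lines differed in 158 genes with that filter and 251 with the replicate block. Of the lists 1 passed with an estimated correlation and 1 with fry, against 14, and leaving out 1 line gave 9 (without iKras1) to 15 (without E-11). Yap1 differed by 0.76 to 0.98 leaving out 1 line and passed in no setting. Its differences in single lines moved by more than the spread between arrays in 36 cases and not in 28, and with the other probe set 9 of 16 lines changed sign, none of them E-1, E-2, E-5 or E-12. With the mean of all probe sets, r with Yap1 was 0.17 for Birc2, −0.03 for Birc3, 0.38 for its targets and 0.48 for proliferation. Leaving out 1 of the 13 lines, r with Yap1 was 0.18 to 0.44 for Birc2, 0.24 to 0.40 for Birc3, 0.16 to 0.39 for its targets and −0.25 to 0.22 for proliferation. Genes near the level of the trp control probe sets, which include 6 of the 8 named lower genes, are limited by signal over background.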

Other observations

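The test of chromosomes below was written before its result was seen.

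Xist, the RNA that silences an X chromosome, was 6.18 in E-4, 5.44 in E-5 and 6.30 in E-15 and 9.86 in E-1, and was 12.02 or more in the other 12 relapse lines, with 12.09 in iKras1 and 11.11 in iKras2. In E-3, a window on chromosome 3 had a median of −2.06. The genes more than 1 below the batch median there were S100a1, S100a13, S100a16, Sprr2h, Sprr1a and Ivl, genes of calcium binding and epidermal barrier. In E-4 a window on chromosome 4 around Nfib and Psip1 had a median of 1.31. In E-7 a window on the same chromosome had 1.43, with Rgs3, Tnc and Trim32 among the genes more than 1 above the batch median. The gene set for this scan held 10029 genes with a mean above 6, and 14 regions in 10 lines had windows beyond all shuffles.

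Whole chromosomes also stood apart in single lines. As a hypothesis, gains and losses of chromosomes would move the median of all their genes, and 94 of 360 pairs of chromosome and line lay beyond the range of 100 shuffles, 57 above 0.10 and 37 below −0.14. Among them were chromosome 8 in E-5 (0.56), chromosome 16 in E-8 (0.54), chromosome 15 in E-4 (0.53), chromosome 12 in E-5 (−0.41) and chromosome 9 in E-12 (0.35), the chromosome that carries Yap1. No DNA measurement was analysed here.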
